A study of Homo sapiens with 5 samples.

How the data were processed

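The series holds 5 poly(A) RNA libraries of HEK293 cells at 18 h after transfection: 1 mock, 2 with siRNAs against DICER1 and 2 with siRNAs against DROSHA. The labels give an Illumina TruSeq library protocol. Per the submitters' processing notes, CASAVA 1.8.2, STAR, HTSeq and edgeR were used with the human build hg19; the notes give no role, order or further version for these tools. The authors deposited 1 table of raw read counts per gene symbol for 18257 genes, whole numbers with no normalization. Of these genes 2602 had no read in any library. Columns were matched to samples by name, and 0 columns were left unused. Whether counting used strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart.

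From the deposited counts, genes with at least 1 CPM in at least 2 of the 5 libraries were kept, which left 12234 genes holding 99.9% of the reads. TMM factors and the quasi-likelihood F test came from edgeR 4.0.16 in R 4.3.3, with group as the only term and all 5 libraries in one fit. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The mock is a single library, so the spread comes from the siRNA pairs with 2 residual degrees of freedom, and the mock is assumed to vary like them. The common biological coefficient of variation was 8.51%. Standard errors are the log2 fold change divided by the square root of the F statistic. Contrasts were DICER1 against mock, DROSHA against mock, DICER1 against DROSHA, and the mean of both knockdowns against mock.

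Of 27 gene lists fixed before the data were examined, 22 had at least 5 tested members. They were tested with camera in limma 3.58.1, with a preset correlation of 0.01 on log2 CPM with a prior count of 2, and with DICER1 and DROSHA left out. Adjustment ran over the lists within each of 3 contrasts. No list passed with an estimated correlation or with fry, in any contrast. Noncoding microRNA hosts, microRNA hairpin genes, replication-dependent histones, mitochondrially encoded genes and snoRNA hosts had 1, 0, 0, 0 and 0 tested members and were not analysed here, nor were the AGO genes, which were not matched in the table by either name. "Higher" or "lower in both libraries" means that each siRNA library lay on the same side of the mock, or both DICER1 libraries on the same side of both DROSHA libraries. Of all tested genes, higher and lower together, 73.1% met this in DICER1 against mock. The share was 63.9% in DROSHA against mock and 40.9% in DICER1 against DROSHA.

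Named genes followed a rule fixed before the data were examined: DICER1, DROSHA and DGCR8; the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 CPM and a consistent side; and up to 4 members with the smallest p of each list described. Where fewer than 5 genes were called, which held in every comparison, the 10 with the smallest unadjusted p under the same conditions were named as not past the test. REST, CELSR3, BBC3, ZMAT3, UCHL1, DPYSL3 and the members called over a list alone that fall outside this rule were chosen after their values were seen.

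Library pairs differed by more than counting noise: the chi-square statistic per degree of freedom over 10364 genes lay between 2.84, for the DICER1 pair, and 10.7, and was 8.48 for the DROSHA pair. Named genes were followed across settings in their own comparison only, a choice made after small values of genes in other comparisons were seen to change sign. For correlations between responses, 100 data sets with no change were simulated with negative binomial counts, with dispersions scaled by 1.1 so that the spread within siRNA pairs matched. For a scan of 3' UTRs, GENCODE 29 transcripts on GRCh38 supplied 3' UTR sequences for 17698 gene symbols, older symbols being matched through NCBI synonyms. The files use hg19, so no coordinates are given. In 10452 genes with at least 50 nt of 3' UTR, log2 ratios had UTR length, GC content and expression regressed out, and genes with and without each of 15575 7-mers were compared in 9 contrasts, with 100 permutations of genes giving the range of z expected by chance. Of microRNA families, 20 were looked at, and the z limit of 2 used for them was set after the values were seen.

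The steps were tested on simulated data drawn from the real means and library sizes, with 200 genes changed in 12234. For DICER1 against mock the test called 37.3% of genes changed 1.5-fold, 83.6% changed 2-fold and 97.0% changed 4-fold, with 16 of 161 calls false, a larger share than the adjusted p limit of 0.05 allows. For DROSHA against mock the shares were 35.8%, 68.7% and 98.5%, with 4 of 139 calls false. These data sets used the trended dispersion alone, so the shares are optimistic for genes that vary more. They are also optimistic because many changed genes loosen the adjusted p limit, while in the real comparisons with the mock 1 gene passed. NEK7 at 2.43-fold and VMA21 at 2.24-fold did not pass in DICER1 against mock. A list of genes raised in the DICER1 libraries passed camera with the preset correlation (adjusted p = 1.12e-07) and not with an estimated one (adjusted p = 0.462), and 0 of 21 unchanged lists passed. The simulated genes had no correlation with each other, so this test cannot show how often the preset calls unchanged lists of correlated genes. In the real data the estimated correlation was 0.43 for cholesterol synthesis genes, 0.13 for the neuronal and heat shock lists and 0.099 for zinc finger genes. It was 0.016 for immediate early and mitotic genes. For the unfolded protein and ATF4, miR-17~92 and G1/S lists it was 0.0024, -0.0049 and -0.00055, below the preset, and their calls were lost too. The simulated list failed without any correlation, so a call lost this way does not by itself show correlated genes. A 7-mer with a planted log2 shift of 0.05 was the most depleted in 15 of 20 trials, and in 20 of 20 at 0.1. Alternatives were DESeq2 1.42.0, other normalizations and filters, only the groups compared, a replicate block, leaving out each library, and a fold minimum. The edgeR likelihood ratio test, lists without genes that carry a depleted 7-mer, and lists with the trend in GC, length and expression removed were chosen after seeing the data. Python 3.11.15 with scipy 1.17.1 ran the 3' UTR scan.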

Results

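Poly(A) RNA was sequenced from HEK293 T-REx Flp-In cells, a human embryonic kidney line that here carries a FLAG-tagged copy of DICER1. Cells were sampled 18 h after transfection with siRNAs against DICER1, the cytoplasmic nuclease that cuts microRNA precursors, or against DROSHA, the nuclear nuclease that acts one step earlier. There was 1 mock library and 2 libraries for each enzyme, each made with a different siRNA. Per the design text, the knockdowns assess how Dicer binding affects gene regulation, with DROSHA knockdown and mock as the controls. Total counts were 8497016 for the mock, 7620206 and 8285001 for DICER1 siRNA 1 and 2, and 8736455 and 7812093 for DROSHA siRNA 1 and 2. The 10 most abundant genes held between 2.90% and 2.96% of the counts of each library, and 12234 genes were tested. The labels do not say whether the libraries came from separate cultures, so p-values measure only the spread between these libraries.

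In each knockdown the mRNA of the targeted enzyme fell. DICER1 stood at 242.91 CPM (counts scaled by library total and TMM factor) in the mock and at 70.9 ± 4.48 CPM (SD, n = 2) in the DICER1 siRNA libraries, a loss of 70.8%. Its log2 fold change was -1.78 ± 0.12 (SE), with an adjusted p of 0.0260 in edgeR's quasi-likelihood test. DROSHA stood at 191.33 CPM in the mock and at 41.5 ± 0.513 CPM (SD, n = 2) in the DROSHA siRNA libraries, a loss of 78.3%, with a log2 fold change of -2.20 ± 0.09 and an adjusted p of 0.000882 in the same edgeR test. DROSHA mRNA was at 101.2% of the mock level after DICER1 siRNA, and DICER1 mRNA at 126.4% after DROSHA siRNA, neither past the test. DICER1 reads can come from the native gene or the tagged insert, which the counts do not separate. DGCR8, the RNA-binding partner of DROSHA, whose own mRNA holds a hairpin that the DROSHA complex can cut, stood at 121.81 CPM in the mock, 130.5 ± 2.16 CPM with DICER1 siRNA and 180.5 ± 10.7 CPM with DROSHA siRNA (SD, n = 2). Its log2 fold change of 0.57 ± 0.10 in DROSHA against mock had an edgeR adjusted p of 0.979 over all genes and 0.0206 adjusted over the list alone, the list being the microRNA biogenesis genes. Without DROSHA siRNA 1 it was 0.50 with an adjusted p of 0.0436 over all genes.

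**Figure D1:**
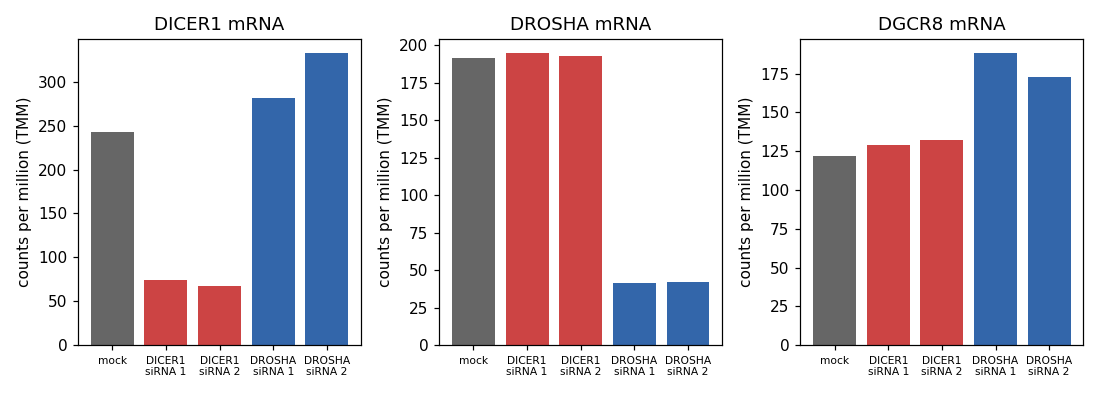
CPM of DICER1, DROSHA and DGCR8 mRNA in each of the 5 libraries, 1 bar per library, with no error bars. DICER1 is lowest in both DICER1 siRNA libraries (74.03 and 67.69 CPM) and DROSHA in both DROSHA siRNA libraries (41.19 and 41.91 CPM).

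In the DICER1 knockdown the unfolded protein and ATF4 response genes rose as a group, as did neuronal genes, immediate early genes and targets of the miR-17~92 microRNA cluster. Heat shock chaperones, cholesterol synthesis genes and mitotic genes fell as groups. These 7 calls come from camera with its preset correlation, and none was kept with an estimated correlation (adjusted p from 0.419 to 0.737). Among single genes, DICER1 was the only one past the test. The neuronal list had a median log2 change of 0.27 over 18 members, with 13 members higher and 2 lower in both DICER1 libraries. Among all tested genes, 73.1% were either higher or lower in both, so such counts of members are to be read beside that share.

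The unfolded protein and ATF4 list had a median 1.16-fold above the mock over 36 members, with 29 higher in both DICER1 libraries and 1 lower (camera, adjusted p = 3.37e-09, and adjusted p = 0.419 with an estimated correlation). The edgeR likelihood ratio test called HERPUD1, DDIT4 and SESN2 over all genes (adjusted p = 0.00784, 0.00784 and 0.0186). In edgeR's quasi-likelihood test no member passed over all genes, and 6 passed upward adjusted over the list alone. These include HERPUD1, a part of the machinery that removes misfolded proteins from the endoplasmic reticulum, with a log2 fold change of 0.66 ± 0.10 (SE), SESN2 with 0.67 ± 0.12, DDIT4, an inhibitor of mTORC1, with 0.82 ± 0.15, and DNAJB9, a chaperone of the endoplasmic reticulum, with 0.71 ± 0.16. The neuronal list (camera, adjusted p = 0.000168, and adjusted p = 0.607 with an estimated correlation) also had 6 members past the quasi-likelihood test upward adjusted over the list alone and none over all genes. The likelihood ratio test called CHGA, CHGB and SNAP25 over all genes. CHGA and CHGB, cargo proteins of secretory granules, had log2 fold changes of 1.40 ± 0.31 and 1.18 ± 0.28, SNAP25, a part of the synaptic fusion complex, 2.07 ± 0.51, and the adhesion molecule L1CAM 1.31 ± 0.33. The immediate early list had a median 1.11-fold above the mock over 24 members (camera, adjusted p = 0.000389, and adjusted p = 0.560 with an estimated correlation), with DUSP1 at 0.54 ± 0.12 and KLF4 at 0.55 ± 0.20. No immediate early member passed over all genes or adjusted over the list alone.

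The miR-17~92 target list, chosen as textbook targets of a microRNA cluster abundant in dividing cells, had a median 1.09-fold above the mock over 48 members, with 31 higher in both DICER1 libraries and 11 lower (camera, adjusted p = 0.0216, and adjusted p = 0.560 with an estimated correlation). Its leading members were the kinase MINK1 at 0.51 ± 0.12, the retinoblastoma relative RBL2 at 0.31 ± 0.09, FYCO1 at 0.35 ± 0.11 and the lipoprotein receptor VLDLR at 0.49 ± 0.16. The 19 heat shock chaperones had a median log2 change of -0.10, with 14 lower in both DICER1 libraries (camera, adjusted p = 0.00781, and adjusted p = 0.618 with an estimated correlation), among them HSPA4L at -0.35 ± 0.10 and DNAJA1 at -0.19 ± 0.07. The 25 cholesterol synthesis genes had a median of -0.10 (camera, adjusted p = 0.0282, and adjusted p = 0.737 with an estimated correlation), with STARD4 at -0.39 ± 0.12 and CYP51A1 at -0.51 ± 0.23. The 40 mitotic genes had a median of -0.04 (camera, adjusted p = 0.0282, and adjusted p = 0.607 with an estimated correlation), with 20 lower in both DICER1 libraries and the spindle checkpoint gene MAD2L1 at -0.84 ± 0.17. With the trend in GC content, length and expression removed, the mitotic median turned to 0.0067 (adjusted p = 0.749) and the heat shock list no longer passed (adjusted p = 0.0645), at a median of -0.0813. In these 4 lists no member passed edgeR's quasi-likelihood test over all genes or adjusted over the list alone. The edgeR likelihood ratio test called MAD2L1 over all genes (adjusted p = 0.0163). Without DICER1 siRNA 1 the miR-17~92, mitotic, cholesterol and heat shock lists no longer passed (adjusted p = 0.0862, 0.0634, 0.0776 and 0.0634), at medians of 0.15, -0.0758, -0.085 and -0.12. Without DICER1 siRNA 2 the mitotic and cholesterol lists did not pass (adjusted p = 0.154 and 0.110), at medians of -0.0644 and -0.0779. Without genes that carry a depleted 7-mer in the 3' UTR, the neuronal list had a median of 0.14 (adjusted p = 0.106) and the mitotic, cholesterol and heat shock lists did not pass either (adjusted p = 0.0642, 0.0696 and 0.0696), at medians close to those with all genes, -0.0355, -0.092 and -0.0884.

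Of single genes, those with the smallest p after DICER1 did not pass the test and are given as values. NEK7, a mitotic kinase, had 908 counts in the mock and 321 and 388 in the DICER1 libraries, a log2 fold change of -1.28 ± 0.11 (edgeR adjusted p = 0.0876). VMA21, an assembly factor of the vacuolar proton pump, stood at -1.16 ± 0.14, TMEM33 at -0.75 ± 0.09, DENND5A at -0.69 ± 0.10 and CHUK, a kinase of the NF-kappaB pathway, at -0.85 ± 0.15. On the higher side CPLX2, a regulator of synaptic vesicle fusion, had 25 counts in the mock and 109 and 213 in the DICER1 libraries, a log2 fold change of 2.75 ± 0.46, and the glycine transporter SLC6A9 stood at 1.33 ± 0.22. VMA21, TMEM33, DENND5A, CHUK and NEK7 each hold a depleted 7-mer, AATCTAA, in the 3' UTR, as do 1281 of 10452 scanned genes. It was picked from these same libraries, so holding it is no independent support. In all, 668 genes had an unadjusted p under 0.05, where 612 are expected by chance, 304 of them higher and 364 lower. DESeq2 called 5 genes, DICER1, NEK7, VMA21, CPLX2 and CELSR3. The call of DICER1 itself was lost without either DICER1 library, which leaves 1 library against 1. Its log2 fold change stayed as large, at -1.85 without DICER1 siRNA 1 and -1.71 without DICER1 siRNA 2.

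The remaining lists did not pass in DICER1 against mock. Targets of let-7, another abundant microRNA family, had a median log2 change of 0.0002 over 49 members (camera, adjusted p = 0.583), and targets of miR-15 and miR-16 0.07 over 31 members (adjusted p = 0.391). The microRNA biogenesis list had a median of 0.05 (adjusted p = 0.800), protein-coding microRNA hosts a median of 0.006 and a mean of -0.02 (0.567), and double-stranded RNA binding proteins -0.06 (0.371). Interferon-stimulated genes stood at -0.006 (adjusted p = 0.640), p53 targets at 0.05 (0.775), and G1/S replication genes at 0.05 (0.203). Nuclear genes of oxidative phosphorylation had a median of -0.03 (adjusted p = 0.203), cytosolic ribosomal proteins 0.04 (0.194, and a median of 0.0897 with adjusted p = 0.000560 with the GC, length and expression trend removed), mRNA decay genes 0.02 (0.663) and RNA polymerase III and tRNA processing genes -0.009 (0.594). TGF-beta and matrix genes had a median of -0.006 and a mean of 0.01 (adjusted p = 0.915), zinc finger genes at -0.01 (0.733), and markers of other cell types, with 5 tested members, at 0.04 (0.343). SESN2 and the apoptosis gene BBC3 of the p53 list passed upward and ZMAT3 downward adjusted over the list alone.

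In the DROSHA knockdown the unfolded protein and ATF4 genes, immediate early genes, miR-17~92 targets and zinc finger genes rose as groups and cholesterol synthesis genes fell, by camera with its preset correlation. None of the 5 calls was kept with an estimated correlation (adjusted p from 0.687 to 0.834), and the zinc finger median turned to -0.0082 without DROSHA siRNA 2 and was 0.0962 without siRNA 1. DROSHA was the only gene past the test. The unfolded protein and ATF4, immediate early, miR-17~92 and cholesterol lists moved the same way in the DICER1 knockdown. Both comparisons use the same single mock library, so an unusual mock cannot be told apart from an effect of the knockdowns there. Compared directly, DICER1 and DROSHA libraries did not pass for the miR-17~92, immediate early and cholesterol lists (camera, adjusted p = 0.929, 0.307 and 0.279). They did for the unfolded protein and ATF4 list (0.00650). The unfolded protein and ATF4 list had a median 1.08-fold above the mock, with 23 of 36 members higher in both DROSHA libraries (camera, adjusted p = 0.000314, and adjusted p = 0.687 with an estimated correlation). Its leading members were DNAJB9 at a log2 fold change of 0.80 ± 0.16, HERPUD1 at 0.40 ± 0.10, the stress-induced transcription factor ATF3 at 0.32 ± 0.11 and PPP1R15A, a phosphatase subunit of the stress response, at 0.34 ± 0.11. The miR-17~92 targets had a median 1.07-fold above the mock, with 22 members higher in both libraries and 7 lower (camera, adjusted p = 0.0121, and adjusted p = 0.687 with an estimated correlation). MINK1 stood at 0.53 ± 0.12, FYCO1 at 0.39 ± 0.11, RBL2 at 0.27 ± 0.09 and KLF4 at 0.57 ± 0.20. The cholesterol list had a median log2 change of -0.21, with 16 of 25 members lower in both libraries (camera, adjusted p = 0.000650, and adjusted p = 0.818 with an estimated correlation), among them the desaturase SCD at -0.33 ± 0.11, IDI1 at -0.29 ± 0.10 and CYP51A1 at -0.65 ± 0.24. This median was -0.04 in DROSHA siRNA 1 and -0.30 in DROSHA siRNA 2, and without siRNA 2 the list no longer passed (adjusted p = 0.257). Without DROSHA siRNA 1 the unfolded protein and ATF4 list did not pass, at a median log2 change of 0.0957 against 0.11 with all libraries.

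The immediate early list had a median log2 change of 0.09, which was 0.14 without DROSHA siRNA 1 (camera, adjusted p = 0.0173, and adjusted p = 0.722 with an estimated correlation), with JUN at 0.29 ± 0.10 and EGR2 at 1.43 ± 0.53. The 427 zinc finger genes had a median of 0.05 (camera, adjusted p = 0.0382, and adjusted p = 0.834 with an estimated correlation). That median came from DROSHA siRNA 2, at 0.10, against -0.01 in siRNA 1. Without siRNA 2 the zinc finger and immediate early lists did not pass (adjusted p = 0.877 and 0.0815), at medians of -0.0082 and 0.11, while cytosolic ribosomal proteins, heat shock chaperones and TGF-beta and matrix genes did (0.0129, 0.0214 and 0.0351). Without genes that carry a depleted 7-mer, the miR-17~92, immediate early and zinc finger lists did not pass (adjusted p = 0.0503, 0.183 and 0.0687), although their medians were larger, at 0.13, 0.14 and 0.0662. With the GC, length and expression trend removed, cytosolic ribosomal proteins passed, at a median of 0.0775 (adjusted p = 0.00714). In these 5 lists no member passed edgeR's quasi-likelihood test with all libraries, over all genes or adjusted over the list alone. Single genes with the smallest p, none past the test apart from DROSHA, included NR1H2, a nuclear receptor for oxysterols, at 1.01 ± 0.14 (edgeR adjusted p = 0.979), with 282 counts in the mock and 546 and 570 in the DROSHA libraries. RNH1, the cytosolic ribonuclease inhibitor, stood at 0.57 ± 0.09, NRBP1 at 0.76 ± 0.13 and CHPF2 at 0.55 ± 0.10. On the lower side LBR, a receptor of the inner nuclear membrane, stood at -0.38 ± 0.06, APP, the amyloid precursor gene, at -0.38 ± 0.06, and KIAA1147 at -0.56 ± 0.11. These 3 genes each hold a 7-mer depleted in a DROSHA siRNA library, ATAGAAT or GTGACTT, in the 3' UTR. Of 10452 scanned genes 1537 hold ATAGAAT and 1529 hold GTGACTT, and DNAJB9, which was higher in the DROSHA libraries, also holds GTGACTT. The 7-mers were picked from these same libraries, so holding them is no independent support. In all, 451 genes had an unadjusted p under 0.05, fewer than the 612 expected by chance, and DESeq2 called 1 gene, DROSHA. Without DROSHA siRNA 1 the count of called genes went from 1 to 225, and without DROSHA siRNA 2 to 4.

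The remaining 17 lists had adjusted p between 0.103 and 0.990 in DROSHA against mock. Let-7 targets had a median log2 change of 0.04 (camera, adjusted p = 0.187), and heat shock chaperones -0.08 (adjusted p = 0.118). The neuronal list stood at -0.10 (adjusted p = 0.229), with 2 of 18 members higher and 8 lower in both DROSHA libraries.

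Compared directly, the DICER1 libraries had higher neuronal genes, unfolded protein and ATF4 genes and G1/S replication genes than the DROSHA libraries, and lower mitotic genes and zinc finger genes, by camera with its preset correlation. None of the 5 calls was kept with an estimated correlation (adjusted p from 0.481 to 0.742), and the zinc finger difference was 0.0013 without DROSHA siRNA 2 and -0.1178 without siRNA 1. This comparison sets 2 libraries against 2 and leaves the mock out of the contrast. Only the targeted genes passed singly, DROSHA at a log2 fold change of 2.22 ± 0.08 and DICER1 at -2.12 ± 0.10. The neuronal list had a median 1.34-fold higher in the DICER1 libraries, with 13 of 18 members above both DROSHA libraries and 1 below (camera, adjusted p = 1.92e-06, and adjusted p = 0.481 with an estimated correlation). In edgeR's quasi-likelihood test 8 of its members passed upward adjusted over the list alone and none over all genes. DESeq2 called CHGB, INA, CHGA and SYP over all genes. CHGB stood at 1.66 ± 0.23, INA, a neuronal intermediate filament, at 0.69 ± 0.10, CHGA at 1.62 ± 0.25 and the synaptic vesicle protein SYP at 1.37 ± 0.26.

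**Figure D2:**
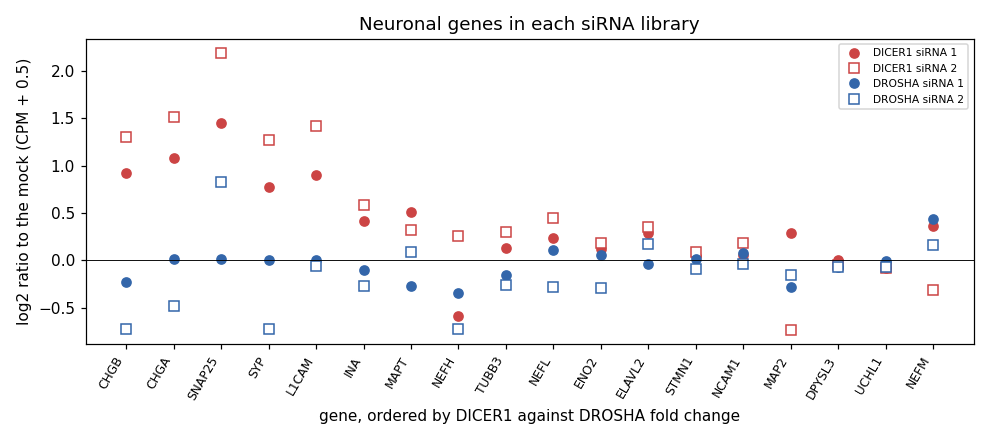
Log2 ratio to the mock of each tested neuronal gene, computed from CPM with 0.5 added, with 1 point per siRNA library and genes ordered by the DICER1 against DROSHA fold change. CHGB, CHGA, SYP and L1CAM lie above the mock in both DICER1 libraries and near or below it in both DROSHA libraries, while members such as UCHL1 and DPYSL3 lie near 0 throughout.

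The unfolded protein and ATF4 list was 1.09-fold higher at its median over 36 members (camera, adjusted p = 0.00650, and adjusted p = 0.481 with an estimated correlation), with SESN2 at 0.51 ± 0.10, DDIT4 at 0.54 ± 0.12 and STC2 at 0.35 ± 0.10. G1/S replication genes had a median log2 difference of 0.09 over 39 members (camera, adjusted p = 0.00603, and adjusted p = 0.481 with an estimated correlation), with the DNA glycosylase UNG at 0.26 ± 0.06 and TYMS, which makes thymidylate, at 0.25 ± 0.07, while CCNE2 stood at -0.43 ± 0.10. Mitotic genes had a median of -0.08, with 17 of 40 members lower (camera, adjusted p = 0.00603, and adjusted p = 0.481 with an estimated correlation). MAD2L1, at -0.80 ± 0.14, passed edgeR's quasi-likelihood test adjusted over the list alone, and DESeq2 called it over all genes (adjusted p = 0.00259). ANLN stood at -0.45 ± 0.12, CCNA2 at -0.28 ± 0.09 and AURKA at -0.23 ± 0.08. The zinc finger genes had a median of -0.06 (camera, adjusted p = 0.00603, and adjusted p = 0.742 with an estimated correlation), with an adjusted p of 0.918 without DROSHA siRNA 2. Without DICER1 siRNA 1 or DROSHA siRNA 2 the G1/S list and the unfolded protein and ATF4 list did not pass. Their median log2 differences were 0.0906 and 0.1272 without DICER1 siRNA 1, and 0.0654 and 0.0656 without DROSHA siRNA 2. With all libraries they were 0.09 and 0.12. Without DROSHA siRNA 1 the mitotic list did not pass (adjusted p = 0.0988), while cholesterol synthesis genes did at a median of 0.14 (0.00812). Nuclear genes of oxidative phosphorylation passed without DROSHA siRNA 2, at -0.084 (adjusted p = 0.00506), and without genes that carry a depleted 7-mer, at -0.04 (0.0249). With the trend in GC content, length and expression removed, the mitotic list no longer passed (camera, adjusted p = 0.364), at a smaller median of -0.0424.

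Genes with the smallest p that did not pass were VMA21 at -1.22 ± 0.12 (edgeR adjusted p = 0.0953), TMEM33 at -0.78 ± 0.08, DENND5A at -0.82 ± 0.09, CHUK at -1.03 ± 0.13 and SESN3 at -0.90 ± 0.11 on the lower side. On the higher side were CPLX2 at 2.85 ± 0.36, SCG3, another secretory granule protein, at 4.92-fold, and APP at 0.46 ± 0.05. DGCR8 stood at -0.47 ± 0.08. In all, 1020 genes had an unadjusted p under 0.05, against 612 expected by chance. DESeq2 called 24 genes, among them VMA21, CPLX2, CHUK, SCG3, CHGA and CHGB. The count of 2 called genes became 427 without DROSHA siRNA 1, 18 without DROSHA siRNA 2, 4 without DICER1 siRNA 1 and 1 without DICER1 siRNA 2, where DICER1 had an adjusted p of 0.103.

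Taking both knockdowns as one group against the mock, 1 gene passed, DROSHA, with 451 genes at an unadjusted p under 0.05, and DESeq2 added NEK7. Without DROSHA siRNA 1 the count was 46, and without either DICER1 library 0. The 2 siRNAs of each enzyme were compared through pairs that share no library. Across 12232 genes, the DICER1 siRNA 1 minus DROSHA siRNA 1 differences correlated with those of siRNA 2 at r = 0.21, and the crossed pairs at r = 0.18, while simulated unchanged libraries gave between -0.04 and 0.03 for the direct pairing. Genes are not independent replicates, so these values describe the libraries. The DICER1 and DROSHA fold changes against the shared mock correlated at r = 0.52 across genes, below the mean of 0.67 from 100 simulated data sets with no change, and their covariance was 0.0303 against a simulated 0.0386. At an unadjusted p under 0.05, 98 genes were higher in both comparisons and 34 lower in both, where independent lists would share 6.26 and 5.85. These 2 comparisons use the same mock library, which cannot be split, so the lists are not independent.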

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

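The tests of REST's 3' UTR and of STMN2 were chosen after the results they measure were seen, while the test of REST-repressed genes was set before those genes' values were seen but after the neuronal pattern was noticed.

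The DICER1 and DROSHA libraries differed by a direct test in 7 results. The targeted genes did, with log2 differences of -2.12 for DICER1 and 2.22 for DROSHA. By camera with its preset correlation, the neuronal list differed by a median of 0.42, the unfolded protein and ATF4 list by 0.12, G1/S replication genes by 0.0904, mitotic genes by -0.0772 and zinc finger genes by -0.0588. None of these 5 lists passed with an estimated correlation.

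Neuronal genes were higher in the DICER1 than in the DROSHA libraries by camera with its preset correlation, a call not kept with an estimated correlation (adjusted p = 0.481). Neuronal cells in the DICER1 cultures are argued against by STMN2, among the most abundant mRNAs of neurons, which had 3 counts in the 2 DICER1 libraries together, with an exact Poisson 95% upper bound of 8.77 that covers counting error only, against 169 for SNAP25. Lower activity of REST, the repressor of neuronal genes outside the nervous system, cannot be told apart from other causes. Of 26 listed REST-repressed genes outside the neuronal list 16 were tested. Their median log2 difference was 0.90, above all 10000 expression-matched random lists, whose central 95% ended at 0.19. In all, 14 were higher in both DICER1 libraries than in both DROSHA libraries. None passed edgeR's quasi-likelihood test over all genes (lowest adjusted p = 0.423). Against the mock their median was 0.69, while SYN1 and RAB3A stood at -0.07 and -0.42. REST-repressed genes are themselves largely neuronal, so any cause that raises neuronal genes would raise them. The random lists were drawn gene by gene and leave out correlation between genes. Whether siRNA sites in REST lowered it cannot be told apart from other causes, because REST holds 1 AATCTAA site and was lower than the mock in both DICER1 libraries, as the written prediction asked, but at -0.33 ± 0.24 (SE; edgeR unadjusted p = 0.207) it missed a p limit that was added to that prediction. REST was -0.61 ± 0.20 from the DROSHA libraries (edgeR adjusted p = 0.523), in part because it stood at 0.28 in the DROSHA libraries against the mock (0.48 and 0.0435 without DROSHA siRNA 1 and 2), and it was -0.38 without DROSHA siRNA 2, -0.40 without DICER1 siRNA 2 and -0.82 without DROSHA siRNA 1 (adjusted p = 0.0401), and against the mock -0.58 and -0.12 without DICER1 siRNA 1 and 2, so an effect of DICER1 loss on REST stays open as untested.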

How the results depend on the processing

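Where a library was left out, a lone library was assumed to vary like the rest; the likelihood ratio test and the lists without 7-mer genes or with the trend removed were chosen after seeing the data. Main counts of called genes were 1, 1, 2 and 1 for DICER1 against mock, DROSHA against mock, DICER1 against DROSHA and both against mock. In that order DESeq2 gave 5, 1, 24 and 2, the likelihood ratio test 29, 3, 130 and 7, and no low-count filter 3, 1, 12 and 1. Using only the groups compared gave 4 in DICER1 against mock and could not be done for both against mock, which needs all groups. RLE factors, library totals, the stricter filter and the fold minimum moved no count. Leaving out 1 library gave 0 to 5, 1 to 225, 1 to 427 and 0 to 46; the highest of each came without DROSHA siRNA 1, where the spread comes from the DICER1 pair alone. The siRNA numbers only name different molecules, and the deviations of same-numbered libraries correlated at 0.02; the replicate block gave 1, 1, 2 and 0, and with it the mitotic list in DICER1 against mock lost its call (adjusted p = 0.0550). The cause of these differences was not tested. The count of lists, 7, 5 and 5 in the first 3 comparisons, was 0, 0 and 0 with an estimated correlation and with fry, 6, 5 and 5 with the replicate block, 3, 2 and 6 without genes that carry a depleted 7-mer, and 6, 6 and 4 with the trend removed. Without 1 library it was 3 to 7, 4 to 5 and 3 to 5. In DICER1 against mock the neuronal list lost its call without the 7-mer genes (adjusted p = 0.106). The median of mitotic genes in DICER1 against mock turned to 0.0067 with the trend removed, and without DROSHA siRNA 2 that of zinc finger genes turned to -0.0082 in DROSHA against mock and 0.0013 in DICER1 against DROSHA (0.0962 and -0.1178 without siRNA 1). The agreement of siRNAs, r = 0.21, was 0.29 at a mean of at least 5 CPM and 0.18 with crossed pairs, and the correlation of responses, 0.52, was 0.44 at that filter. REST and the named genes, each of these followed only in the comparison that names it, kept their direction in every setting run; the call of DICER1 was lost in 3 fits that left out a DICER1 library. With 1 mock and 2 residual degrees of freedom, simulated 1.5-fold changes in single genes were called in 37.3% and 35.8% of cases in the 2 comparisons with the mock.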

Other observations

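The 7-mers below were found in these libraries, and every test here was chosen after the result was seen, most with the tested value already known; a count of lower genes without these 7-mers, planned earlier, is not used because the 7-mers were picked on the same libraries.

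Depleted 7-mers in 3' UTRs differed between the DICER1 and DROSHA libraries and between the siRNAs of each enzyme, while AATCTAA was depleted in both DICER1 libraries. Of 15575 7-mers, AATCTAA was the most depleted in DICER1 siRNA 1 (z = -9.92) and in DICER1 siRNA 2 (z = -21.0), ATAGAAT in DROSHA siRNA 1 (z = -16.6) and GTGACTT in DROSHA siRNA 2 (z = -24.5), where permuted genes reached -5.67 at the lowest. CTATGTT (z = -9.82) and GATATTA (z = -9.44) were depleted in DICER1 siRNA 1, against z of -2.20 and -0.558 in DICER1 siRNA 2. AATCTAA, CTATGTT, ATAGAAT and GTGACTT occur in the mRNA of the targeted gene, as do 41.6% of scanned 7-mers for DICER1 and 26.6% for DROSHA, while GATATTA does not. NEK7, VMA21, TMEM33, DENND5A and CHUK hold 2, 3, 5, 1 and 2 AATCTAA sites in their 3' UTRs.

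Genes lower in both DICER1 libraries numbered 58 at an edgeR unadjusted p under 0.01, beside 58 higher, among genes with at least 50 nt of 3' UTR. Together these are about as many as chance alone gives at this limit, and none passed the edgeR test over all genes. At an unadjusted p under 0.05 this comparison had 668 genes, where 612 are expected by chance. A trend in UTR length, GC content or expression cannot be judged from these genes. The fitted trend gave 12.1% of the change at the median of the 58 lower genes and 31.1% at the upper end of their central 95%. Those genes were picked for a large change, which makes a small share likely in advance. AATCTAA mRNAs were lower in both libraries (z = -9.92 and -21.0) but by different amounts (z = 17.2 for siRNA 1 minus 2, permuted 95% range -1.65 to 2.52). DICER1 mRNA fell to like levels with DICER1 siRNA 1 and 2 (74.03 and 67.69 CPM). The unequal amounts therefore argue against loss of DICER1 mRNA as the only source of the AATCTAA depletion. For the part that both libraries share, off-target repression through siRNA seed sites and loss of DICER1 itself cannot be told apart. Neither DICER1 protein nor the siRNA sequences were used here.

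The mRNAs with the site of the miR-17 family, GCACTTT, were higher than in the mock in all 4 siRNA libraries, with z of 4.11, 3.45, 6.63 and 9.36 in DICER1 siRNA 1 and 2 and DROSHA siRNA 1 and 2, at mean shifts of 0.02, 0.02, 0.03 and 0.06 on the log2 scale. These z values were computed with the fitted trend in UTR length, GC content and expression removed, so that fitted trend is not their source. In the DROSHA libraries z (6.63 and 9.36) was above that of every permuted 7-mer (6.10 and 5.07 at the highest). In the DICER1 libraries z (4.11 and 3.45) was below the highest permuted (4.75 and 5.00), so chance among the scanned 7-mers stays open there. Over all siRNA libraries z was 8.25 with the trend removed and 2.13 before, so the pattern rests on that correction and a trend of another form stays open. An unusual mock cannot be told apart as a part of the rise, because the same single mock is in each of these contrasts (lowest z = 3.45). Contrasts without the mock argue against it as the only source. For DICER1 minus DROSHA z was -5.04 (lowest permuted -4.72), and for DROSHA siRNA 1 minus 2 it was -4.72 (lowest permuted -4.67). The DICER1 siRNAs did not differ in this way (z = -0.287). Competition of transfected siRNAs with microRNAs and loss of microRNAs cannot be told apart, because both predict a rise in all 4 libraries (4 of 4) and no control siRNA was analysed here.

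Of 20 families looked at, 4 were higher in every siRNA library at z above 2, miR-17, miR-19, miR-92 and miR-130, while let-7 had z of 0.947, -0.23, 1.70 and 0.689. The miR-130 site, TTGCACT, overlaps the miR-19 site, TTTGCAC, and the miR-17 site, GCACTTT. A stretch of 3' UTR can therefore hold several of these sites, and the families are not independent observations.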
